A study of Mus musculus with 9 samples.

How the data were processed

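Two-colour Agilent mouse arrays were used, with Cy3-labelled RNA of CCAT-transfected, sorted Neuro2A cells and Cy5-labelled control RNA on every array, per the labels. The deposited values were log10 ratios of both channels, made with the Rosetta Luminator system per the design text. The background correction, the dye normalization and the order of the ratio were not given in the sources used here. The base of the log was inferred from the values, which were capped at exactly -2 on the FL arrays, and array medians lay between -0.0046 and -0.0011. No background or saturation flags were used here. Samples were grouped by their titles and source names into FL against untransfected cells, DTA against untransfected cells and FL against empty vector, with 3 arrays each. The labels write both DTS and DTA for the truncated construct. The text of one channel of FL replicate 1 against empty vector names the other dye than its label field, and that array correlated at 0.83 and 0.81 with the others of its group.

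Ratios were converted to log2. Features were named through the platform annotation, with symbols checked against the mouse RefSeq gene table of assembly GRCm38.p6, from which no coordinates were used. On the 6 arrays 18218 features had 1 gene symbol, 16 had several and 4159 had none. On the 3 arrays these numbers were 32042, 47 and 11701. Features with several symbols or none were left out of the gene tests. Features of a gene were averaged, which concerned 1193 and 8266 genes with more than 1 feature. No value was missing, and 344 to 384 features per array on the 6 arrays, and 724 to 747 on the 3, had a ratio of exactly 0.

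Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with Benjamini-Hochberg adjustment and a threshold of 0.05. The 6 arrays against untransfected cells shared 1 fit with 4 residual degrees of freedom, which gave both groups and their difference. The 3 arrays against empty vector had a fit of their own with 2. The spread between arrays, as the median SD of a gene, was 0.071 for FL, 0.041 for DTA and 0.041 for FL against empty vector. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 22 lists of a comparison. No list stayed called with an estimated correlation. That setting rests on only the 4 or 2 residual degrees of freedom and so has little power. A call lost under it does not show that the list did not shift. The lists were recalled CCAT targets, calcium, potassium, and sodium, HCN and TRP channels, glutamate and GABA receptors, connexins, axon guidance, calcium transport, interferon, inflammation, unfolded protein response, heat shock, p53, cell cycle, immediate early, cholesterol, oxidative stress, neuronal, glial, fibroblast and immune markers, and ribosomal proteins. Groups, tests, lists, the rule for named genes and most alternatives were set before the data were examined. The rule named the 10 highest and 10 lowest mean ratios past the threshold with all arrays in one direction (for FL minus DTA, groups that did not overlap), leaving out clone, gene model and pseudogene symbols, Cacna1c and Gjb5, up to 4 members per list with the smallest p, and up to 10 genes shared by the FL comparisons.

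The steps were tested on simulated data with 100 genes changed per size. For FL, 95% of genes changed by 0.5 and 98% of genes changed by 1 on the log2 scale were recovered among 16504 genes, with 12 false calls. For DTA these were 95%, 98% and 10, for their difference 93%, 98% and 12, and for FL against empty vector, among 19087 genes, 92%, 99% and 23.

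Alternatives were array centring, quantile normalization, single features, the median over features, ratios of 0 as missing, a filter on barely varying genes (largest absolute log2 ratio under 0.2), robust eBayes, a group fitted alone, the replicate number as a block, leaving out each array, a 2-fold threshold, an estimated correlation and fry for lists, and the sign turned. Added after seeing the data were limma's treat at 1.5-fold, matching by accession, leaving out genes on a plateau, and camera and fry for a list of HIF target genes. A plateau is a value shared by many features of an array, found where the number of features within 0.00025 on the log10 scale most exceeded that expected from a window of 0.005, and a gene was left out when a feature lay on it on at least 2 arrays of a group. A first version of this search picked an ordinary dense value on 4 arrays and was replaced after its result had been seen. A list of HIF target genes was also written after the data had been seen, and its members whose values had been seen were kept apart. One of these, Ddit4, was moved to the seen members only after a first run, which lowered the tested median. Figures were drawn with matplotlib 3.10.9.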

Results

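Gene expression was measured on 9 two-colour Agilent arrays of mouse Neuro2A cells, a neuroblastoma line that grows in culture. CCAT is the C-terminal part of the calcium channel CaV1.2, and the study asked which genes it regulates as a transcription factor. Cells received a plasmid coding for the last 503 amino acids of the channel (full-length, FL) or the last 280 (truncated, DTA, described in the labels as lacking the activation domain), and GFP-positive cells were sorted 24 hours later. On 6 arrays the control channel held RNA of untransfected cells, with 3 arrays for FL and 3 for DTA. On the other 3 arrays, of another platform, FL was set against cells that received the empty plasmid. The 6 arrays had 22393 features and 16504 named genes, and the 3 arrays had 43790 features and 19087 named genes. Across named genes, arrays of one group correlated with Pearson's r of 0.84 to 0.90 for FL, 0.92 to 0.95 for DTA and 0.81 to 0.83 for FL against empty vector. The DTA array of replicate 3, whose treatment text names the full-length construct while its title and source name the truncated one, correlated at 0.92 and 0.95 with the other DTA arrays and at 0.73 to 0.79 with the FL arrays. The number of arrays limits the precision of every value.

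Values below are log2 ratios, and a positive value is taken as higher in the CCAT channel. This order is likely, not stated. It rests on the design text, which says that the plasmid alone raised some genes, and on interferon genes, which had strongly positive ratios against untransfected cells and ratios near 0 against empty vector. All directions below turn together if the order is the reverse. CCAT RNA carried Cy3 and control RNA Cy5 on every array. A gene-specific dye effect was therefore not separated from the ratios of a single group. It cancels in the difference between FL and DTA only where it was equal on both sets of arrays, which was not tested. Features of 1 gene often differed: where a feature was at least 1.5-fold higher with FL than in untransfected cells, with a median of 0.78, other features of the same gene with another accession had a median of 0.11, and against empty vector these medians were 0.73 and 0.05.

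Against untransfected cells, FL-transfected cells had far higher levels of interferon-stimulated genes. Cxcl10, a chemokine induced by interferon, was 41.7-fold higher (log2 ratio 5.38, SD 0.14, n = 3). Gbp3, an interferon-induced GTPase, had a log2 ratio of 5.47 (SD 1.00), Isg15, a ubiquitin-like modifier, 4.27 (SD 0.08), and the antiviral genes Ddx60, Ifit1 and Mx2 had 3.96, 3.78 and 3.41. Gjb5, a connexin gene, was 9.07-fold higher (3.18, SD 0.62), and Pdk1, which restrains pyruvate oxidation, and Fmn1, an actin-nucleating formin, rose by 3.04 and 3.01. The lowest ratios were those of Necab1 (-2.13, SD 0.54), a calcium-binding protein, Styk1 (-2.04), Ces1f (-1.92), Sowaha (-1.82), Fam81a (-1.64), the potassium channel subunit Kcnv1 (-1.63), the receptor Gpr12 (-1.57) and Artn (-1.53, SD 0.11), a neurotrophic factor. Limma adjusted p for these genes ranged up to 0.00817 (Sowaha).

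Of 40 measured interferon-stimulated genes, 35 rose and 3 fell (35 and 3 adjusted over the list alone), and 26 rose at least 2-fold, with a median log2 ratio of 1.31. Bst2 (2.72) and Irgm1 (2.97) were among those with the smallest p. Camera gave adjusted p = 4.23e-09 for this list and adjusted p = 0.267 with an estimated correlation. Of 20 cholesterol synthesis genes 19 rose and 0 fell (19 and 0 adjusted over the list alone), among them Hmgcs1 (1.79), Lss (1.78), Insig1 (1.62) and Hsd17b7 (1.61), with a camera adjusted p = 1.03e-08 and adjusted p = 0.325 with an estimated correlation. Among 30 genes of the unfolded protein response and ATF4, 20 rose and 6 fell, among them the chaperone Hspa5 (1.37) and the phosphatase subunit Ppp1r15a (1.43), with adjusted p = 0.00522 and, with an estimated correlation, adjusted p = 0.355. Immediate early genes rose in 22 of 33 and fell in 6, with Ier3 at 1.77, Klf2 at 1.69 and Jun at 1.24 while Dusp6 fell by 0.61 (adjusted p = 0.00751, and adjusted p = 0.355 with an estimated correlation). Heat shock genes rose in 11 of 17 (2 fell), p53 targets in 12 of 22 (1 fell) and oxidative stress and metallothionein genes in 11 of 17 (3 fell). Bag3 (0.92), Cdkn1a (1.02) and Gclc (0.85) were examples, and each of these 3 lists had a camera adjusted p = 0.0151 and adjusted p = 0.325 with an estimated correlation. Adjusted over the list alone, the counts were 20 up and 6 down for the unfolded protein response, 22 and 6 for immediate early genes, 11 and 3 for heat shock, 12 and 1 for p53 targets, and 12 and 3 for oxidative stress.

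Glutamate and GABA receptor genes fell in 13 of 28 and rose in 4 (13 and 4 adjusted over the list alone), with Grin2d at -1.42 (SD 0.09) and Gabra5 at -0.55. This list had a camera adjusted p = 0.0431, which became adjusted p = 0.325 with an estimated correlation, 0.058 without FL replicate 1 and 0.072 without FL replicate 3. The 31 cytosolic ribosomal protein genes, 19 of which fell and 6 of which rose (19 and 6 adjusted over the list alone), also passed camera (adjusted p = 0.0282; adjusted p = 0.370 with an estimated correlation). However, 13 of them had a feature on a value that many features of an array shared within 0.00025 on the log10 scale, at a median log2 ratio of -0.19, and without these genes camera gave adjusted p = 0.402. The median log2 ratio was -0.144 over all 31 genes and -0.095 over those off the shared value. The median of the shorter list thus kept its sign, but camera did not call that list, so a shift of the remaining genes is not shown. The other lists did not pass camera. Members that rose and fell numbered 4 and 12 of 24 voltage-gated calcium channels, 4 and 16 of 37 potassium channels, 7 and 9 of 25 sodium, HCN and TRP channels, 4 and 5 of 13 connexins and pannexins, 15 and 21 of 53 axon guidance genes, 10 and 11 of 37 calcium transport and calmodulin genes, 11 and 6 of 23 inflammatory genes, 21 and 13 of 40 cell cycle genes, and 17 and 11 of 35 neuronal markers. Markers of other cell types did not rise as groups, with 1 up and 5 down of 11 for glia, 3 and 9 of 14 for fibroblasts and 0 and 6 of 13 for immune cells. Of 8 genes recalled as CCAT targets, a list chosen from work on these samples and so not independent evidence, 4 rose (Gjb5 and Fmn1 among them) and 3 fell, among them the potassium channel Kcnn3 (-0.98, SD 0.06) and Trpv4 (-0.93).

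In all, 11513 of 16504 genes passed the limma test at an adjusted p of 0.05, 5720 higher and 5793 lower. The median absolute log2 ratio of these genes was 0.28, and 268 of them changed at least 2-fold, 197 higher and 71 lower. P-values measure only the spread between arrays, which may be technical, since the labels do not say that replicates came from separate cultures.

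**Figure D1:**
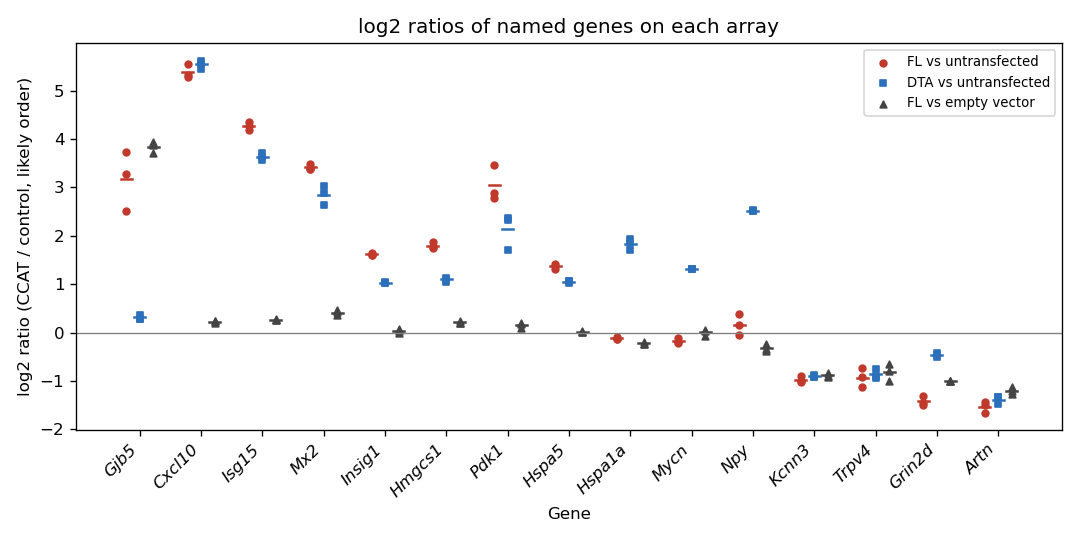
Log2 ratio (vertical axis) of 15 genes (horizontal axis) on each array, for FL and DTA against untransfected cells and FL against empty vector; points are arrays and bars are means of 3 arrays. Cxcl10 lay above 5 in both comparisons with untransfected cells and at 0.23 against empty vector, while Gjb5 lay at 3.18, 0.31 and 3.84.

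Cells with the truncated construct shared the interferon rise. Cxcl10 was 46.6-fold higher than in untransfected cells (5.54, SD 0.09, n = 3), followed by Gbp3 (4.74), Fmn1 (4.08), Tango6 (3.92, SD 0.08), Vmn1r219 (3.89), a vomeronasal receptor gene, Isg15 (3.63), Ddx60 (3.59), Nabp2 (3.18), Egln3 (3.18), an oxygen-sensing hydroxylase, and Camp. Gjb5 was 0.31 (SD 0.05) with a limma adjusted p of 0.224 in the fit shared with the FL arrays, where its SD was 0.62, and it passed with DTA fitted alone (adjusted p = 0.00125) or without FL replicate 3 (0.0269). Leaving out 1 gene with a clone name, the lowest ratios were those of Styk1 (-2.61), Necab1 (-2.11), the opioid precursor Pdyn (-2.10), Arhgap6 (-1.84), the kinase Prkd1 (-1.83), Sowaha (-1.83), Cts3 (-1.80), Adgrl4 (-1.74) and Bank1 (-1.64). Arhgap6 had an adjusted p of 0.0514 without DTA replicate 2.

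Interferon-stimulated genes rose in 33 of 40 and fell in 2, 19 of them rising at least 2-fold (camera adjusted p = 3.43e-07; adjusted p = 0.398 with an estimated correlation). Cholesterol synthesis genes rose in 16 of 20 and fell in 2, with Hsd17b7 at 1.71 and Insig1 at 1.03 (adjusted p = 2.32e-04). Immediate early genes rose in 23 of 33 and fell in 6, with Klf2 at 1.62 and Jun at 1.07 (adjusted p = 0.00713), and heat shock genes rose in 12 of 17 and fell in 3, with Hspa1a at 1.84 (SD 0.12) and Hsph1 at 0.95 (adjusted p = 0.0141). With an estimated correlation each of these 3 lists had an adjusted p = 0.568. Over the list alone, the adjusted counts of higher and lower genes were 33 and 2 for interferon, 17 and 2 for cholesterol, 23 and 6 for immediate early and 12 and 3 for heat shock genes. Neuroblast and neuronal markers rose in 19 of 35 and fell in 10, with the oncogene Mycn 1.31 higher, and did not pass camera (adjusted p = 0.198). No other list passed camera, except that oxidative stress genes did without DTA replicate 3 (adjusted p = 0.0319, against 0.0593 with it). The limma test called 11854 genes, 5896 higher and 5958 lower, of which 384 changed at least 2-fold (298 higher, 86 lower), and without DTA replicate 3 it called 10113.

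FL and DTA were compared directly on the same platform, which asks what depends on the part missing from the truncated construct. The contrast also holds any difference in construct level or extent of transfection, which were not measured here. DTA was not set against empty vector, so effects of the missing part are not told apart from these. Gjb5 was 7.30-fold higher with FL than with DTA (difference in log2 ratio 2.87, adjusted p = 0.00176). Col11a2 (1.84), Mpv17 (1.84), Ctnnal1 (1.53), Ppef2 (1.46), Cnmd (1.21) and Ifit1 (1.19) were also higher with FL. Of genes higher with DTA, Tango6 differed by -3.43, Vmn1r219 by -2.82, Tnni2, a troponin, by -2.64, Nabp2 by -2.53, Ltbp4 by -2.42, Npy, a neuropeptide, by -2.36, H2-Ob by -2.29, Lrrc34 by -2.08 and Rspo2 by -2.04. The heat shock gene Hspa1a (-1.96) and Mycn (-1.48, adjusted p = 1.8e-04) were higher with DTA as well. Of 53 genes at least 2-fold higher with DTA, 30 were at least 2-fold up in DTA against untransfected cells and under 1.5-fold changed in FL. Of 16 genes at least 2-fold higher with FL, 6 were at least 2-fold up in FL and under 1.5-fold changed in DTA.

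Cholesterol synthesis genes were higher with FL in 15 of 20 and lower in 0 (17 and 0 adjusted over the list alone), with Idi1 at 0.77, Dhcr7 at 0.76, Sc5d at 0.61 and Insig1 at 0.59 (camera adjusted p = 4.04e-07; adjusted p = 0.529 with an estimated correlation). Interferon-stimulated genes were higher with FL in 15 of 40 and lower in 2 (17 and 2 adjusted over the list alone), with Isg15 at 0.64 and Ifit2 at 0.58 (adjusted p = 0.00243; adjusted p = 0.529 with an estimated correlation). Genes of the unfolded protein response were higher in 14 of 30 and lower in 3 (16 and 5 adjusted over the list alone), with Pdia4 at 0.52 and Dnajb9 at 0.46 (adjusted p = 0.00482; adjusted p = 0.688 with an estimated correlation). For p53 targets, with 5 of 22 higher (Gadd45a at 0.57) and 0 lower, camera gave adjusted p = 0.0433, and adjusted p = 0.688 with an estimated correlation. For calcium channels, with 4 of 24 lower (Cacng8 at -0.32) and 0 higher, it gave adjusted p = 0.0487, and adjusted p = 0.724 with an estimated correlation. Over the list alone these counts were 5 and 0 for p53 targets and 0 and 4 for calcium channels. Among all 16504 genes 2996 were higher and 2650 lower. The 5 of 22 higher and 4 of 24 lower are thus near the shares of all genes in those directions. The p53 call was lost without DTA replicate 1 (adjusted p = 0.113) or FL replicate 1 or 2 (0.0520 and 0.0702), and the calcium channel call without DTA replicate 1 (0.0990), FL replicate 1 or 3 (0.0633 and 0.0728) or with centring (0.0525). Ribosomal protein genes were lower with FL in 21 of 31 and higher in 6 (23 and 6 adjusted over the list alone; camera adjusted p = 1.78e-04), but without the 13 genes on the shared value camera gave adjusted p = 0.792, and with an estimated correlation adjusted p = 0.529. Limma called 5646 genes, 2996 higher and 2650 lower with FL, and 69 of them differed at least 2-fold, 16 higher and 53 lower. Without DTA replicate 1, 2 or 3, 3731, 3595 and 3415 genes were called.

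Against empty vector, the comparison that the study added to control for the plasmid, Gjb5 had the highest ratio, 14.3-fold (3.84, SD 0.11, n = 3, limma adjusted p = 0.0021). Among genes whose symbols are not clone, gene model or pseudogene names, next came the olfactory receptor gene Olfr1168 (2.05), Kcp (1.98), Vmn1r219 (1.77), Cdon (1.15), a cell-surface receptor, Nabp2 (1.07), Spink10 (1.06, adjusted p = 0.0559 without replicate 1), Vps16 (1.06), Cep295nl (1.05) and Shisa2 (0.98). The 2 features of Vps16 gave 0.33 and 1.78. Every other gene named among the highest or lowest ratios of any comparison, Gjb5 included, was measured by 1 feature. Its value could therefore not be checked against another feature of that platform. The lowest ratios of such genes were those of Olfr1402 (-2.08), the trefoil peptide Tff1 (-1.53), Aspdh (-1.47), Itpripl2 (-1.33), Orly (-1.31), the hormone Amh (-1.30), the transcription factor Pdx1 (-1.23), Tsga8 (-1.22), Oxt (-1.22), the oxytocin precursor, and Artn (-1.20, SD 0.07). The recalled target list, not independent evidence here, had 3 of 8 genes higher (Gjb5, and Rgs5 at 0.79) and 4 lower (Kcnn3 at -0.88 and Trpv4 at -0.82).

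Interferon-stimulated genes had a median log2 ratio of 0.14 against empty vector, with 24 of 42 higher, 2 lower and 0 changed 2-fold (24 and 2 adjusted over the list alone). Ifit1 was 0.47, Mx2 0.41 and Isg15 0.26 higher. Camera called this list (adjusted p = 0.00379; adjusted p = 0.52 with an estimated correlation) and no other. Cholesterol synthesis genes went both ways, with 11 of 20 higher and 5 lower, Hmgcs1 at 0.21 and Mvd at -0.49. Glutamate and GABA receptor genes were lower in 18 of 32 and higher in 5, with Grin2d at -0.997 (SD 0.01), and the list had a camera adjusted p = 0.0667, or 0.0450 without replicate 2. A lower median was not particular to these receptors (-0.139). Immune cell markers had a median of -0.216, with 7 of 13 lower and 0 higher (camera adjusted p = 0.165). The immediate early gene Egr1 was 0.67 higher and the synaptic gene Syn1 fell by 0.60. Limma called 12107 of 19087 genes, 5837 higher and 6270 lower, with a median absolute log2 ratio of 0.20, and 50 changed at least 2-fold, 15 higher and 35 lower. Tested for a change of more than 1.5-fold, a setting chosen after seeing the data, 2 genes passed. Cacna1c, the gene of CaV1.2, had ratios of 0.15 (FL) and 0.27 (DTA) against untransfected cells and -0.05 against empty vector, and since the position of its feature was not used here, these do not check the transfection.

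**Figure D2:**
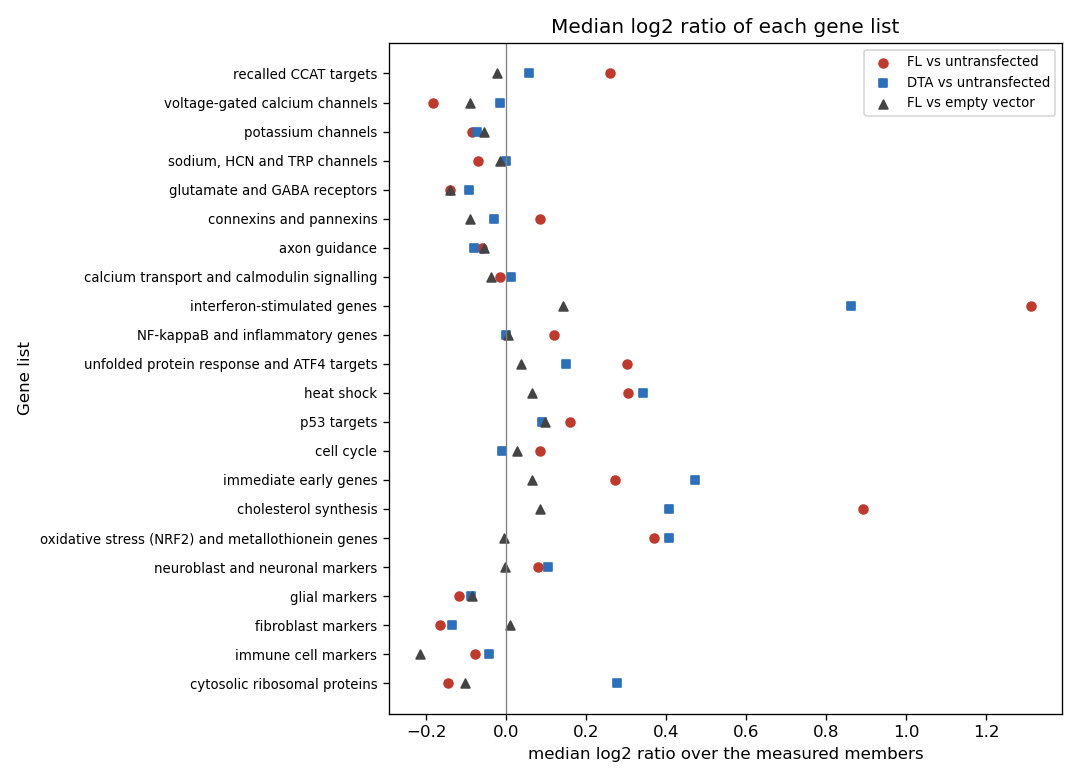
Median log2 ratio (horizontal axis) over the measured members of each of 22 gene lists (vertical axis), for the 3 groups of 3 arrays; no errors are drawn. Interferon-stimulated genes lay at 1.31 and 0.86 against untransfected cells and at 0.14 against empty vector.

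The comparisons overlapped. Of genes changed at least 2-fold, 160 were shared by FL and DTA against untransfected cells, all in the same direction, where independent lists would share 3.56 higher and 0.37 lower genes. The FL and DTA ratios correlated with r = 0.81 across genes, which are not independent replicates, and had a covariance of 0.120. Simulated unchanged groups with 1 shared control extract gave a correlation of 0.75 and a covariance of 0.0060. That correlation was fixed by the simulation, which gave the control and the rest of each array equal variance. It is therefore no measure to set the observed 0.81 against. Part of the overlap may still come from a shared control, which the labels do not describe. The simulation took the size of the control's deviation from the spread between arrays. An extract shared by all arrays adds nothing to that spread, so the simulated covariance sets no upper limit on this part. FL against untransfected cells and FL against empty vector, normalized separately and so not tested against each other, correlated with r = 0.43 (covariance 0.0360). They shared 8 genes changed at least 2-fold, 3 higher and 5 lower, where independent lists would share 0.084 and 0.085. Independent lists leave out gene-specific dye effects, which have the same orientation on all 9 arrays, and any FL RNA used on both platforms, so these overlaps and correlations do not show a shared response to CCAT. Gjb5, Cdon and Vmn1r219 were higher in both, and Artn, Amh, Styk1, Serping1 and Myo1g were lower. Sox3 (-1.18 and -0.99) and Grin2d (-1.42 and -0.997) were close to these. Cdon had an FL adjusted p of 0.0838 without FL replicate 1 and 0.0826 without FL replicate 2, and Vmn1r219 had 0.156 and 0.149, 0.0575 without DTA replicate 2 and 0.0821 with FL fitted alone. DTA against untransfected cells correlated with FL against empty vector with r = 0.30 (covariance 0.0271).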

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

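The tests of the ribosomal and of the both-control patterns were chosen after their results had been seen, and the others before. The following differences between FL and DTA passed limma's test of the difference itself. Gjb5 (2.87), Col11a2 (1.84), Mpv17 (1.84), Ctnnal1 (1.53), Ppef2 (1.46), H1f6 (1.28), Cnmd (1.21), Ifit1 (1.19), Ctsj (1.15) and Cldn19 (1.13) were higher with FL on the log2 scale. Tango6 (-3.43), Vmn1r219 (-2.82), Tnni2 (-2.64), Nabp2 (-2.53), Ltbp4 (-2.42), Npy (-2.36), H2-Ob (-2.29), Lrrc34 (-2.08), Egln3 (-2.05) and Rspo2 (-2.04) were higher with DTA. The calls of H1f6 and Cldn19 were lost without any 1 of DTA replicates 1 to 3 (adjusted p 0.0571 to 0.0927), that of Ctsj without DTA replicate 1 (0.0511) and that of Egln3 without DTA replicate 2 or 3 (0.0529 and 0.0564). For FL, 5 named genes had opposite directions on all arrays against the 2 controls, a difference that was not tested. Their ratios against empty vector were 0.17 for Gpr12, 0.0818 for Pdyn, -0.27 for Egln3, -0.26 for Col11a2 and -0.29 for Ppef2.

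Features with no gene name that had a mean log10 ratio below -0.8 numbered 461 on the FL arrays against untransfected cells and 715 on the arrays against empty vector, while 0 named features lay that low. Over the 461, the array medians were -1.02, -1.46 and -1.55 for FL and -0.32, -0.54 and -0.50 for DTA. These features were chosen for low FL ratios, which by itself favours less low values with DTA. The medians therefore do not show by how much the groups differ.

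The real split into FL and DTA gave 5646 genes and the highest of the other splits gave 0, but 1 of 10 splits is the smallest share possible, so the splits are too few for a share under 0.05. The same holds for the 4 sign patterns of 3 arrays, where only the real one (1 of 4) reached 11513 genes for FL, 11854 for DTA and 12107 for FL against empty vector, and the highest other gave 0 in each.

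Ribosomal protein genes shifted together between FL and DTA. From 53 to 91 features per array shared 1 ratio within 0.00025 on the log10 scale, at log2 -0.21, -0.19 and -0.17 on the FL arrays, 0.26, 0.25 and 0.36 on the DTA arrays and -0.60, -0.62 and -0.62 against empty vector. Spots too bright in both channels are a candidate explanation. Without the 13 of 31 genes on that value, camera gave adjusted p = 0.792, and the median difference went from -0.20 to -0.10, which did not fall under the limit set for this explanation, so it and a real shift cannot be told apart for the remaining genes. With DTA against untransfected cells, 20 of 31 ribosomal genes were higher and 8 lower. Their median went from 0.277 to -0.014 without the genes on the shared value. Against empty vector, where 11 of 32 genes lay on it, the median went from -0.104 to -0.021. No intensities or saturation flags were used here, so the brightness of these features was not measured.

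Genes lower than empty vector by at least 1.5-fold may reflect single probes, and the same doubt holds for the other comparisons. For 183 such features (unadjusted p under 0.01) with another feature of the same gene and a different accession, the chosen features had a median of -0.71 and the others -0.0309, close to the -0.0044 of all features. These medians were 0.73 and 0.05 for features higher than empty vector. Against untransfected cells they were -0.66 and -0.0051 for FL lower, 0.78 and 0.11 for FL higher, -0.70 and -0.06 for DTA lower and 0.82 and 0.12 for DTA higher. All features had medians of -0.017 for FL and -0.018 for DTA, so the others had moved furthest where the chosen ones were higher with FL or DTA. A dye effect, cross-hybridization or other transcripts of a gene stay open in each comparison. Of the 78 genes lower with FL against both controls by the same limits, among them Kcnn3, Trpv4, Sox3 and Artn, the median ratio of the DTA to the FL change was 0.891. As a set, these genes were therefore lower with DTA as well. Dye effects of these probes or a shared control would also give this, so it does not decide whether CCAT lowers them. The 15 that differed between FL and DTA were all further with FL (Grin2d at -1.42 and -0.46). Genes lower or higher against both controls were chosen on their FL ratios and not on DTA, which favours larger changes with FL. For the 9 genes higher against both controls the median ratio was 0.537 and 6 differed between FL and DTA, 5 further with FL and Nabp2 further with DTA. With DTA, 6 of the 9 also passed limma's test in the same direction, Nabp2 at 3.18 against 0.65 with FL. Their rise was thus not confined to FL, though dye effects or a shared control would also give this. A response that needs the full-length construct stays open for the rest of the 9. For the 15 it stays open whether that construct is needed or only gives a larger change (Inhbc at -1.33 with FL and -1.13 with DTA). A response kept by the truncated form stays open for the others of the 78.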

How the results depend on the processing

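Choosing treat, accession matching and the plateau filter came after seeing the data, and the cause was not tested where a setting below moved a value, except that a fold threshold, fewer genes or fewer arrays change counts by construction. Requiring at least 2-fold left 268 genes for FL, 384 for DTA, 69 for FL minus DTA and 50 for FL against empty vector, and treat at 1.5-fold left 492, 734, 30 and 2. Of the 30 genes for FL minus DTA, 1 was higher and 29 lower with FL. Against empty vector, single features gave 26750 calls (43790 features tested) and the filter on barely varying genes gave 7629 (9132 genes tested). Leaving out each array gave 10347 to 11349 genes for FL, 10113 to 12566 for DTA, 3415 to 5836 for FL minus DTA and 8400 to 9788 against empty vector. Camera called 9 lists for FL, 4 for DTA, 6 for their difference and 1 against empty vector. An estimated correlation left 0 lists in each (1, 1, 0 and 1 at an unadjusted camera p under 0.05), fry, which does not compare a list with other genes, called 19, 18, 10 and 19, and leaving out each array gave 8 to 10, 4 to 5, 4 to 6 and 1 to 3 (3 without replicate 2 of FL against empty vector, where glutamate and GABA receptors and ribosomal proteins had adjusted p = 0.0450). Without plateau genes 3 lists stayed for FL minus DTA, where p53 targets and calcium channels had adjusted p = 0.0539. At unadjusted p under 0.01 and 1.5-fold, 878 genes (8768 otherwise) were shared in direction by FL and DTA and 87 (6032 otherwise) by both FL comparisons. With the sign turned, the interferon median of 1.31 became -1.31. Mbp against empty vector went from -0.09 to 0.16 with the median over features. The call of Fmn1 in FL minus DTA was lost with quantile normalization (adjusted p = 0.180) and without DTA replicate 1 (0.0644), 2 (0.0899) or 3 (0.0863). With the replicate number as a block, 4016 genes differed between FL and DTA instead of 5646. Deviations of same-numbered arrays correlated at -0.043, 0.091 and -0.0025, and those of other pairs at -0.082 to 0.069. These values gave no sign of pairing by number, but with 3 arrays per group they cannot exclude it. Centring, quantile normalization, the median over features, robust eBayes and ratios of 0 as missing kept each count of genes within 1.5-fold. Keeping missing values was not run, since no value was missing, and matching by probe name was not run, since features carry numbers. Signal over background was not used here, so dim features could not be left out.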

Other observations

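The HIF tests were set before the values of the tested members were seen, but Ddit4 was taken out of these only after a first run, and camera and fry were added after the results were seen. Genes induced by the oxygen-sensing factor HIF were higher against untransfected cells, where 26 of 30 rose and 0 fell with FL, and 25 rose and 1 fell with DTA. Ndrg1 (2.52 with FL, 1.93 with DTA), Bnip3 (2.77 and 1.66), a mitophagy receptor, the glucose transporter Slc2a1 (2.01 and 1.44), the lactate transporter Slc16a3 (1.68 and 1.07), the collagen hydroxylase P4ha1 (1.34 and 0.86) and the demethylase Kdm3a (1.34 and 1.01) were among them. Against empty vector 13 of 32 were higher and 11 lower, from Gapdh at -0.46 and Aldoa at -0.37 to Ero1a at 0.30 and Adm at 0.33. Of the 6 named genes, Ndrg1 (0.14), Bnip3 (0.15), P4ha1 (0.08) and Kdm3a (0.11) were higher, and Slc16a3 (-0.07) and Slc2a1 (-0.07) lower. FL exceeded DTA in 18 of 30 and was below it in 2, Egln3 and Aldoa.

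A candidate explanation is that the rise comes with transfection or sorting, which the empty vector shares. The list was written after 11 of its 30 measured genes had been seen, so the other 19 were tested. Their median log2 ratio was 0.884 with FL and 0.48 with DTA, above random lists in each case (one-sided permutation p = 1e-04, the smallest that 10000 draws can give; unadjusted camera p = 0.00826 and 0.0210 with an estimated correlation, which random lists leave out). Against empty vector, on a platform normalized separately, 20 such genes had a median of 0.0052 (one-sided permutation p = 0.412, camera p = 0.670 with an estimated correlation, fry p = 0.0268 for a shift upwards). The 19 genes were also higher with FL than with DTA (median difference 0.34, one-sided permutation p = 1e-04, camera p = 0.0108 with an estimated correlation), which a rise of equal size in all transfected and sorted cells would not give, so whether the constructs or the extent of transfection differed stays open.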
